A study of Rattus norvegicus with 2 samples.

How the data were processed

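Total RNA from 2 colonies of C6, a rat glioma cell line, was measured on 1 expression array per colony. Per the labels' protocols, RNA was extracted with a phenol-based reagent, and sense cDNA was fragmented and labelled with biotin using a whole-transcript GeneChip kit. The cells were grown in a medium with 10% serum. The same treatment text, CHIR99021 at 20 µM with forskolin at 100 µM for 35 days, is attached to both arrays, while both titles call the colony undifferentiated. The labels do not say whether these 2 RNA samples were taken before or after that treatment, and no array is labelled as a treated or untreated partner. The colony number in the title was the only label that separated the arrays, and it defined the 2 groups.

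The deposited table holds 1 value per array feature and colony, for 36685 features. The values were used as log2 levels as deposited by the authors, whose steps to make them are not given in the sources used here. No label or header states the scale, and base 2 was inferred because the deposited values reach 13.3, above the largest natural log or base-10 log that a 16-bit scanner can give. Software, background correction, normalization and summarization are among the steps not given. The 2 arrays had nearly the same quartiles (lower quartile 3.17 and 3.16, median 4.34 and 4.31, upper quartile 6.37 and 6.37 in colonies No.4 and No.8), so the deposited values were compared without further scaling. No probe-level signal or detection call was used here, and how far a level lies above background on its own array is not known.

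Features were named through the platform annotation given for this work: 18511 features had exactly 1 gene symbol, 575 had several, and 17599 had none. Features with several symbols or none were left out of every gene result. The identifiers of 18394 of the 18511 features were found in a RefSeq gene table of assembly GRCr8, and no symbol needed updating. The build behind the array annotation is not given in the sources used here, so the table was used for names and gene order only and no coordinates are printed. Of the 18171 genes measured, 286 had 2 or more features, and the feature with the higher mean level stood for the gene. Genes that these tables do not name are not analysed here.

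With 1 array per colony there is no replicate, so no test, p-value or standard error was computed, and nothing here separates a stable difference between the colonies from a difference between cultures or hybridizations. The difference was the level in colony No.8 minus that in colony No.4, in log2 units. A gene was past the floor when its level in at least 1 colony reached 4.33, the median of all values in the table; 11070 genes were. Genes past the floor with a difference of at least 1 (2-fold) were counted. The 36 gene lists, covering 794 measured genes, were fixed before the data were examined. For each list the median difference over all measured members was given with its percentile among 10000 random lists of the same size, drawn with the same number of genes from each of 20 bins of mean level. A list outside the middle 95% of its random lists is said to stand apart, as a description of these 2 arrays. The names printed were chosen by a rule fixed beforehand: the 12 largest differences in each direction among genes past the floor, leaving out placeholder symbols; up to 4 members per list with the largest differences; and fixed cell type markers. Names chosen after their values were seen are marked as such.

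Further planned descriptions were the agreement between the 2 brightest features of the same gene, and the median difference over runs of 25 neighbouring genes past the floor, set against 1000 shuffles of gene order. The alternatives were centring on the median difference, quantile normalization, a loess of the difference on mean level, other floors, an offset of 64 on the linear scale, other choices of feature per gene, other fold sizes, list means, unmatched random lists and runs of 15 or 50 genes or of all measured genes. A floor from olfactory receptor genes, levels raised to the floor or to the 99th percentile of olfactory receptor genes to give folds of dim genes as bounds, the removal of genes shared between lists, 30 families defined by symbol prefix, medians per chromosome, the block of unnamed features and a second list of NRF2 targets were added after the data had been seen; the prefixes of some families were tightened after their members had been seen. Olfactory receptor genes, used as a guide to background, were also defined after their values had been seen, in 3 ways. The definition used takes all genes with an Or or Olr symbol except Olr1, which encodes a receptor for oxidized lipoprotein, and 3 of its 89 genes past the floor differed by 2-fold. With Olr1 included these were 4 of 90, and with Or symbols only 2 of 78.

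The steps were tested on simulated data: noise with a robust spread of the real differences in each level bin was drawn for all genes, and 200 genes were changed by known folds. Over 11012 genes past the floor, 49 of 50 simulated 4-fold changes, 23 of 50 simulated 2-fold changes and 7 of 50 simulated 1.5-fold changes reached 2-fold in the right direction, against 1.04% of unchanged genes. The noise was normal, with a spread taken from the 2 colonies themselves, so 1.04% is no error rate of real arrays. Of 100 simulated lists of 25 genes, 5 stood apart with no shift, 88 with a shift of 0.25 and 100 with a shift of 0.5. Lists without a shift shared the noise of their random lists, so a number near 5 was built in. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.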

Results

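Gene expression was measured in 2 single colonies of C6, a rat glioma cell line used as a model of malignant astrocytic tumours, called here colony No.4 and colony No.8. Both were described as undifferentiated, and whether they had received the drug treatment named in the protocol is not settled by the labels. Each colony was represented by 1 whole-transcript array without replicates, so all values below are single measurements and the number of arrays limits their precision. Of 18171 genes measured, 11070 reached the floor of 4.33 log2 units in at least 1 colony. Olfactory receptor genes, which most cells outside the nose do not express, had a median level of 2.74 and a 95th percentile of 4.43, close to that floor. Across the 11070 genes past the floor, the levels of the 2 colonies correlated with Pearson's r = 0.946 and Spearman's rho = 0.943 (across genes, which are not independent replicates). The middle 50% of the differences lay between -0.22 and 0.30, with a median of 0.04.

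Single genes differed widely between the colonies, with the matrix gene Postn and the kinase gene Prkcb far higher in colony No.8 and the potassium channel gene Kcna1 and the ribonuclease gene Rnase4 far higher in colony No.4. Of the 11070 genes, 322 were at least 2-fold higher in colony No.8 and 284 were at least 2-fold higher in colony No.4, together 5.47% of the genes past the floor. The share depended on the level in the brighter colony. It was 3.47% of 3572 genes below 6, 6.18% of 4823 between 6 and 8, and 6.88% of 2675 from 8 up. The share below 6 was near the 3.37% of olfactory receptor genes past the floor, used below as a guide to background. At least 4-fold differences were found for 59 and 37 genes respectively. Of the genes at least 2-fold apart, 80 of the 322 higher in No.8 and 46 of the 284 higher in No.4 were below the floor in the other colony, where a level cannot be told from background without a detection call. Folds of such genes are given as bounds counted from the floor, written "at least", a choice made after the data had been seen; counted this way, 288 and 267 genes differed by 2-fold. Levels between the floor and 5.67, the 99th percentile of olfactory receptor genes, may be near background too. Of 95 named genes that reached 2-fold, 18 no longer did when both levels were counted from 5.67 at the least, among them Prss23, Disp2, Olig2, Cspg4, Clu, Gbp5, Notum, Fzd1 and Wnt5a.

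Postn, which encodes the matrix protein periostin, was at 5.28 in colony No.4 and 10.45 in colony No.8 (36.0-fold, and at least 27.5-fold counted from 5.67). Prkcb, the beta form of protein kinase C, was at 2.95 and 8.98 (at least 25.1-fold higher in No.8), and Cd55, a complement inhibitor of the cell surface, at 4.09 and 8.43 (at least 17.2-fold). Igfbp5, an insulin-like growth factor binding protein, was 10.8-fold and Fst, which encodes the activin antagonist follistatin, 7.66-fold higher in No.8. The cancer-testis genes Ct55 and Fmr1nb were at least 10.4-fold and at least 8.08-fold higher in colony No.8. The other leading genes in this direction were below the floor in No.4: Plxdc2 (at least 7.41-fold), the sialyltransferase gene St6gal1 (at least 7.15-fold), Pros1, the anticoagulant protein S (at least 6.99-fold), Antxr1 (at least 6.38-fold) and the serine protease gene Prss23 (at least 5.06-fold). From Prkcb to Prss23, the bounds were counted from the floor and would be smaller counted from 5.67. Counted from 5.67, Prss23 did not reach 2-fold.

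In the opposite direction, Kcna1, a voltage-gated potassium channel subunit, was at 8.94 in colony No.4 and 3.80 in colony No.8. Counted from the floor, Kcna1 was at least 24.4-fold higher in No.4. Kcnab1, an accessory subunit of such channels, was 7.26-fold higher in No.4. Rnase4, a secreted ribonuclease, was at 8.74 and 3.12 (at least 21.3-fold higher in No.4, counted from the floor). A second, dimmer Rnase4 feature differed by 0.09, with both colonies below the floor. The next genes were above the floor in No.8 but under 5.67, and their folds are bounds counted from 5.67. The transcriptional coactivator gene Eya2 (8.82 and 4.48) was at least 8.89-fold higher in colony No.4. In deposited values, both above the floor, Eya2 was 20.3-fold higher in No.4. Bounds from 5.67 therefore do not compare with those of Kcna1 and Rnase4. The mitochondrial serine transporter gene Sfxn1 (8.60 and 4.73) was at least 7.61-fold and the growth factor gene Fgf9 (8.09 and 4.43) at least 5.35-fold higher in colony No.4. Scg2, the neuroendocrine secretory protein secretogranin II (8.39 and 4.99), was at least 6.59-fold higher in No.4, the endocytic adaptor gene Dab2 (8.17 and 5.02) at least 5.64-fold, C1qtnf1 (8.13 and 5.07) at least 5.49-fold and the adhesion molecule gene Alcam (7.92 and 4.89) at least 4.73-fold. The pseudogene Rex2l1-ps1 and Disp2, both below the floor in No.8, were at least 6.49-fold and at least 4.84-fold higher in No.4, counted from the floor. Counted from 5.67, these bounds would be smaller, and Disp2 did not reach 2-fold. As a guide to differences that arise near background, with a gene family defined after its values were seen, 3 of the 89 olfactory receptor genes past the floor also differed by at least 2-fold (3.37%, 95% Wilson interval 1.15 to 9.45%, counting error only) and 0 of them by 4-fold.

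**Figure D1:**
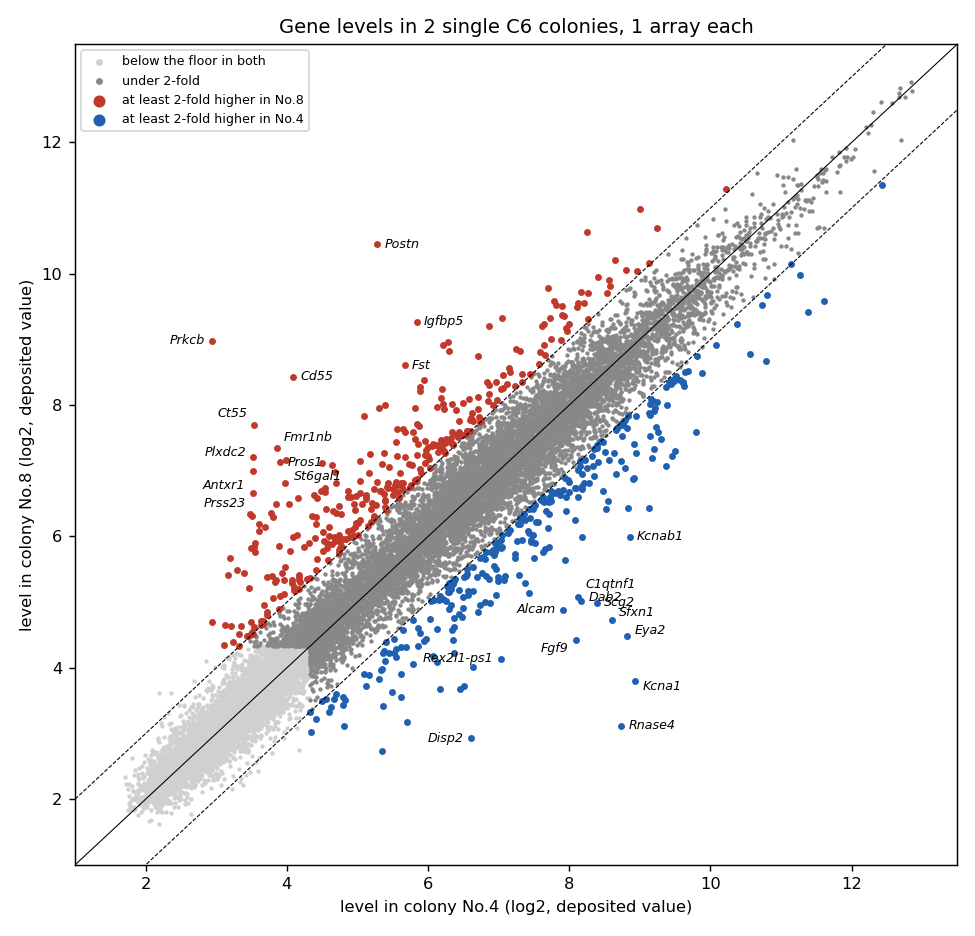
Each point is a gene, with its log2 level in colony No.4 on the x axis and in colony No.8 on the y axis, 1 array each; the solid line marks equal levels, the dashed lines a 2-fold difference, and light grey genes are below the floor in both. The 322 red genes are at least 2-fold higher in No.8, with Prkcb and Postn farthest out in deposited values, and the 284 blue genes at least 2-fold higher in No.4, with Rnase4 and Kcna1 farthest out.

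Grouped by function, 8 of the 36 gene lists stood apart from random lists matched on level, where 1.8 would be expected by chance for independent lists of unrelated genes. The cell cycle, extracellular matrix and cell adhesion lists were higher in colony No.8. The lists of NRF2 and glutathione genes, unfolded protein and amino acid stress genes, glioma tumour genes, matrix proteases and their inhibitors, and interferon response genes were lower in colony No.8. The lists overlap in part, and the percentiles describe these 2 arrays only. The median and the mean differed in sign for the lists of p53 targets, neurons, Notch, antigen presentation, heat shock, growth factors, ion channels and imprinted genes, none of which stood apart.

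**Figure D2:**
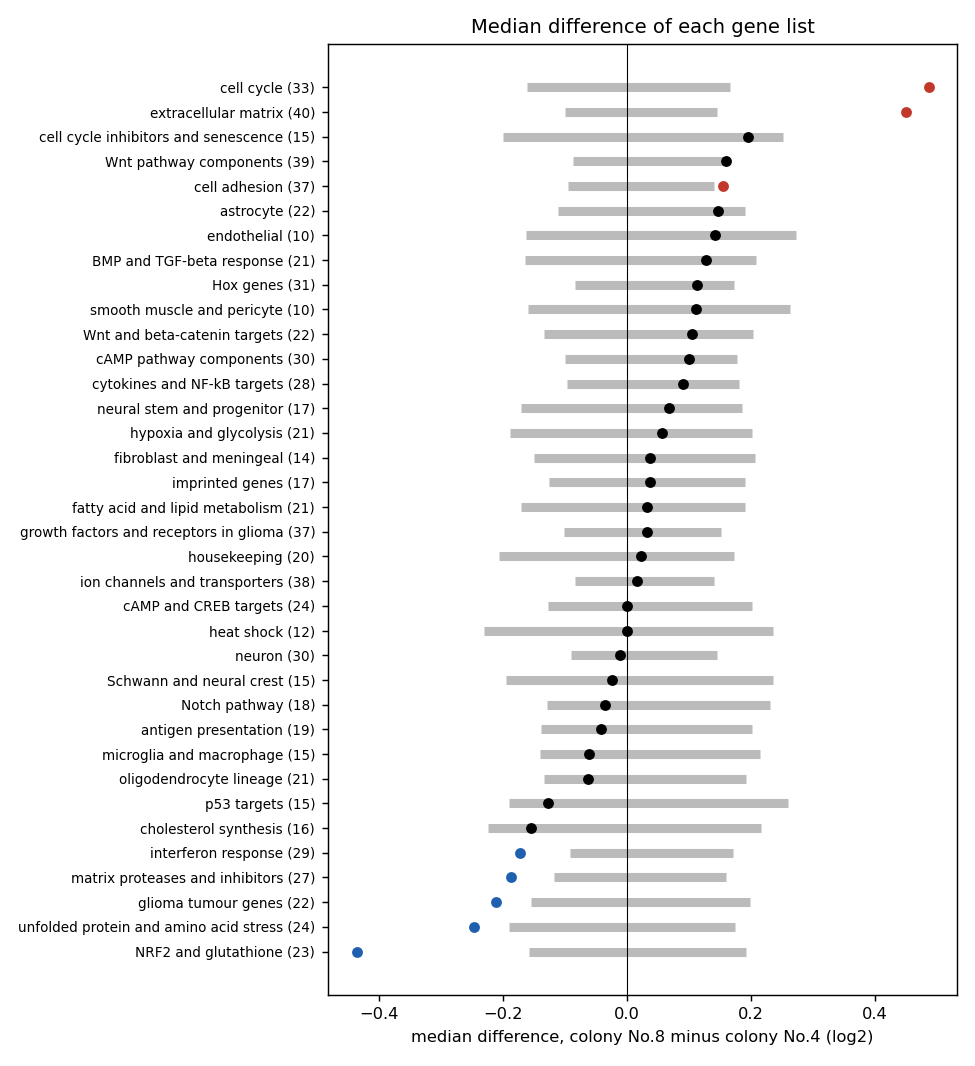
Points show the median log2 difference (colony No.8 minus colony No.4) of each gene list, with the number of measured genes in parentheses. Grey bars span the middle 95% of 10000 random lists matched on level; the 3 red lists lie above and the 5 blue lists below their bars.

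Most cell cycle genes were higher in colony No.8, by amounts that varied between members. The median difference was 0.49 (1.40-fold), at the 100th percentile of random lists, and 30 of the 33 measured members were higher in No.8. Only 2 of them reached 2-fold, the replicative helicase gene Mcm6 (levels 7.97 and 9.13) and the E2F family gene E2f8 (6.42 and 7.52); Foxm1 and Ccne1, a transcription factor of the mitotic programme and cyclin E1, differed by 0.99 each. The proliferation marker Mki67 differed by 0.25, at 10.61 in No.4 and 10.86 in No.8. Named after their values were seen, the replication genes Mcm7 (0.98) and Mcm2 (0.98) differed more than the mitotic genes Cdk1 (0.13) and Aurka (-0.02). Other mitotic genes lay between, such as Plk1 (0.51). The list of cell cycle inhibitors and senescence genes had a median of 0.20 (94.7th percentile) and stood apart with its mean, 0.36, and without genes shared with other lists (median 0.45), with Igfbp5 and Igfbp7 (3.95-fold) higher in No.8 and Gadd45a (10.38 and 9.23) higher in No.4. None of the 14 p53 target genes past the floor differed by 2-fold. The p53 list had a median of -0.13 (8.75th percentile) over all 15 measured members and 0.0045 (40.1th percentile) over those 14, so its direction was not settled, and Cdkn1a, the p53-induced inhibitor p21, was at 8.61 and 8.00.

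Extracellular matrix genes were higher in colony No.8, with a median difference of 0.45 (1.37-fold, 100th percentile), and 32 of the 40 measured members went in that direction. After Postn, the largest differences were those of Col12a1 (6.38-fold), the lysyl oxidase family gene Loxl2 (5.39-fold) and Col1a1, a chain of fibrillar collagen I, at 8.25 in No.4 and 10.64 in No.8 (5.22-fold). Col1a2, the other chain of collagen I, was at 4.57 and 5.06, and Col3a1 at 4.61 and 5.08. These levels were all under 5.67, so they may lie near background. In all, 6 members were at least 2-fold higher in No.8 and 2 at least 2-fold higher in No.4. Matrix proteases and inhibitors were lower in No.8 (median -0.19, 0.32th percentile). Among them Adamts1 was 6.48-fold, the metalloprotease gene Mmp11 4.57-fold and the inhibitor gene Timp3 2.53-fold higher in No.4, while Mmp15 was 2.97-fold higher in No.8. The cell adhesion list had a median of 0.16 (98.6th percentile), with the integrin gene Itga4 (6.31-fold), Cdh2, which encodes N-cadherin (2.90-fold), and Mcam (2.68-fold) higher in No.8 and Alcam higher in No.4. Over the 19 adhesion genes past the floor the median was 0.0021 and the list no longer stood apart.

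NRF2 and glutathione genes were lower in colony No.8, with a median difference of -0.44 (1.35-fold higher in No.4), below all 10000 random lists. Of the 19 members past the floor, 6 were at least 2-fold higher in No.4 and 1, the metallothionein gene Mt1, was at least 2-fold higher in No.8. Nqo1, a quinone reductase and classic NRF2 target, was at 11.60 in No.4 and 9.59 in No.8 (4.04-fold). Another NRF2 gene of the list, Hmox1, went the other way and was 1.54-fold higher in No.8. Of the 23 measured members, 15 were lower and 8 higher in No.8. The glutathione transferase gene Gsta1 was 3.68-fold, the glutathione peroxidase gene Gpx1 2.94-fold and Slc7a11, the cystine transporter, 2.09-fold higher in No.4. Mt1 was 3.50-fold higher in No.8, and its second feature differed by 2.02 in the same direction. Members of the glutathione transferase and metallothionein families have close copies, so single values within them are uncertain.

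Unfolded protein and amino acid stress genes were also lower in colony No.8 (median -0.25, 0.46th percentile), and 16 of 24 members went in that direction. Ddit3, the stress-induced transcription factor CHOP, was at 9.80 in No.4 and 7.59 in No.8 (4.63-fold), and Slc7a11 is a member here too; no other member reached 2-fold, with Vldlr at -0.87 and Chac1 at -0.75. The heat shock list had a median of 0.00 (50.9th percentile), with the small heat shock gene Cryab 2.34-fold higher in No.8. The lists of hypoxia and glycolysis (median 0.06), cholesterol synthesis (-0.16) and fatty acid and lipid metabolism (0.03) did not stand apart. Within them, the glucose transporter gene Slc2a1 was 2.89-fold higher in No.8, the glycolytic regulator gene Pfkfb3 2.21-fold and the phosphatidate phosphatase gene Lpin1 4.90-fold higher in No.4, and 0 of 16 cholesterol synthesis genes reached 2-fold.

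**Figure D3:**
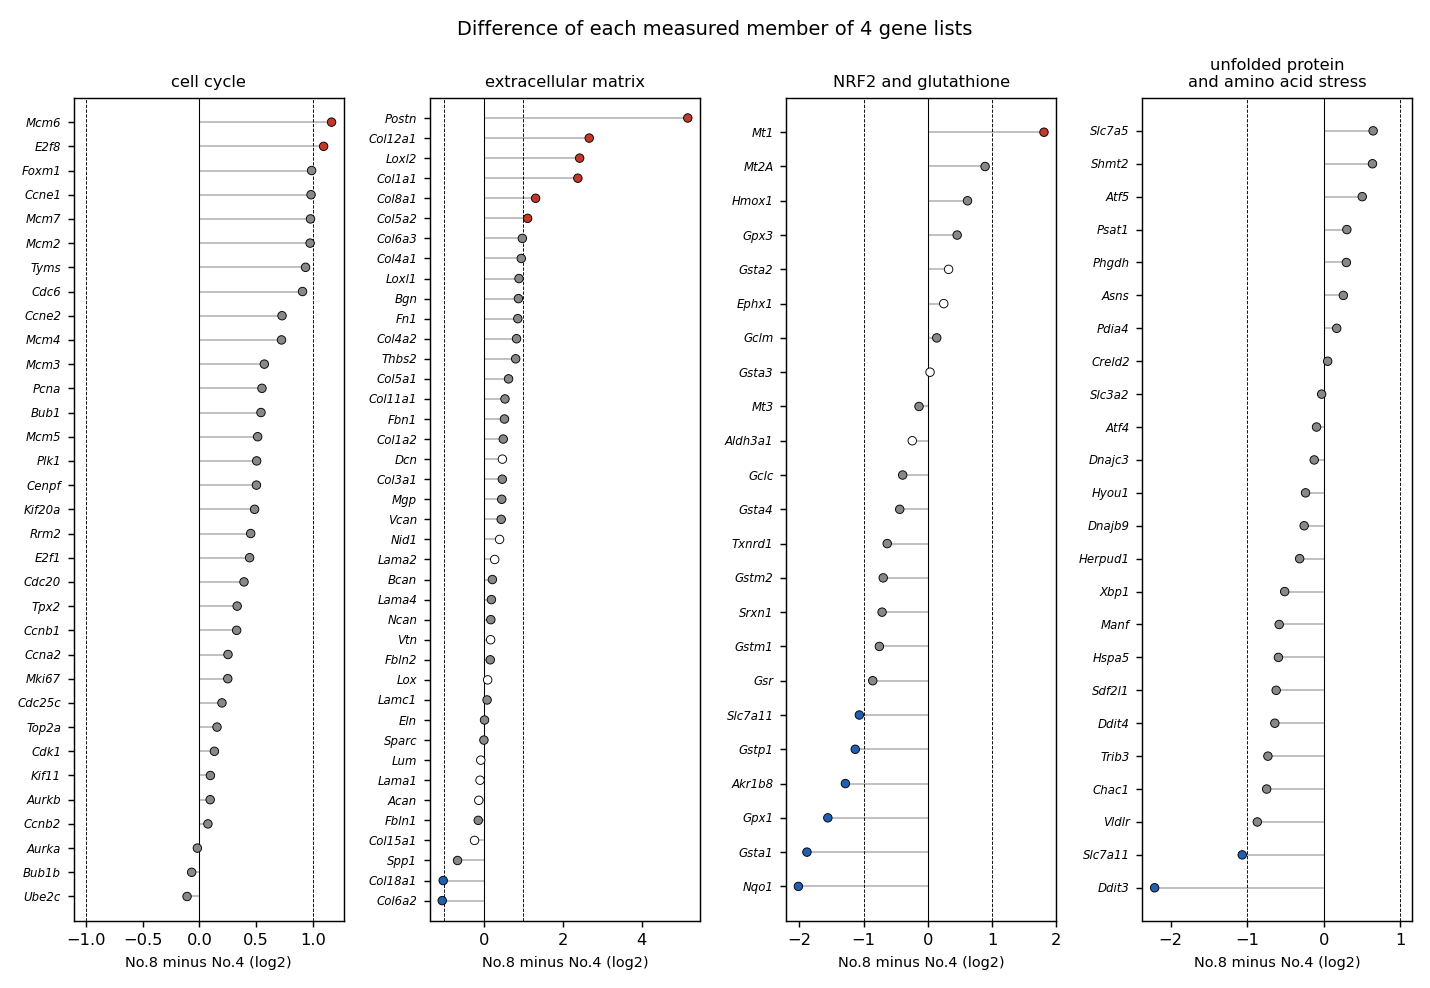
Log2 differences (colony No.8 minus colony No.4) of each measured member of 4 gene lists (cell cycle, extracellular matrix, NRF2 and glutathione, unfolded protein and amino acid stress), 1 array per colony. Red and blue points are past the floor and at least 2-fold higher in No.8 or No.4, grey points are past the floor and under 2-fold, open points are below the floor in both colonies, and dashed lines mark 2-fold; 30 of 33 cell cycle genes lie right of 0 and 15 of 23 NRF2 and glutathione genes left of it.

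Over all measured members no list of neural lineage markers stood apart, while single markers differed, and the oligodendrocyte list was lower in No.8 over its brighter members. Olig2, a transcription factor of the oligodendrocyte lineage, was at 6.36 in No.4 and 4.22 in No.8. Its difference was at least 4.09-fold counted from the floor, but did not reach 2-fold counted from 5.67. Cspg4, the NG2 proteoglycan of oligodendrocyte precursors, was 3.35-fold higher in No.4 (1.62-fold counted from 5.67). Mbp differed by -0.04, and the oligodendrocyte list had a median of -0.06 (13.8th percentile). Of its 13 members past the floor 11 were lower in No.8, with a median of -0.33 at the 0.19th percentile, and its mean of -0.23 stood apart too. In the astrocyte list (median 0.15, 91.9th percentile), Gfap, the astrocytic intermediate filament gene, was at 4.11 and 5.17, both under 5.67. Clu was 2.70-fold higher in No.8 (1.65-fold counted from 5.67). Gja1, which encodes connexin 43, and Id3 were 2.18-fold and 2.13-fold higher in No.4. S100b was at 8.24 and 8.46. Of the neural stem and progenitor genes (median 0.07), Hes1 was 2.68-fold and Bmi1 2.31-fold higher in No.8, Sox2 was at 9.08 and 8.44, and the progenitor filament gene Nes at 9.54 and 9.94. The neuronal list had a median of -0.01, with Tubb3 below the floor in both colonies (4.24 and 4.12). Mapt was 2.23-fold higher in No.8 (1.22-fold counted from 5.67), and Gad1 and Dlg4 were 2.05-fold and 2.11-fold higher in No.4. In the Schwann and neural crest list (median -0.02, and -0.29 at the 1.05th percentile over genes past the floor), the neurotrophin receptor gene Ngfr was 4.84-fold higher in No.8 and Tfap2a 2.10-fold higher in No.4.

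None of the lists of other cell types stood apart over all measured members, and each held genes past the floor: 6 of 15 for microglia and macrophages, 5 of 10 endothelial, 4 of 10 smooth muscle and pericyte, and 8 of 14 fibroblast and meningeal. The microglia and macrophage list had a median of -0.06, with Ptprc, Cx3cr1, P2ry12 and Itgam below the floor in both colonies, and Tmem119 (6.48 and 6.19), Cd14 (6.10 and 6.33) and Trem2 (5.80 and 6.08) past it; 0 of the 6 reached 2-fold. The endothelial list had a median of 0.14, with Tek 2.19-fold higher in No.8 (1.23-fold counted from 5.67), Flt1 at 7.44 and 6.70, and Cdh5, Vwf and Emcn below the floor. In the smooth muscle and pericyte list (median 0.11), Tagln was at 3.92 and 5.45, Pdgfrb was 2.10-fold higher in No.8, and Myh11 was at 4.27 and 4.34. Both Tagln levels were under 5.67, so its difference may lie near background. In the fibroblast and meningeal list (median 0.04), Col1a1 was higher in No.8 and Tbx18 3.07-fold higher in No.4 (1.62-fold counted from 5.67). S100a4 was bright in both (11.28 and 11.27), and Dcn and Lum were below the floor in both.

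The labels name CHIR99021, an inhibitor of the kinase GSK3 that activates Wnt signalling, and forskolin, which raises cyclic AMP, so both pathways were examined. The colonies differed in single members of both. The Wnt and beta-catenin target list had a median of 0.11 (81.0th percentile): Ccn4 was 4.95-fold and Notum 2.51-fold higher in No.8, whereas Axin2, a feedback target of the pathway, was 2.42-fold higher in No.4 (9.61 and 8.33) and Lef1 was at 8.61 and 8.95. The Wnt pathway components had a median of 0.16 (97.4th percentile, just inside the range), with Ror1 4.35-fold and Fzd1 2.32-fold higher in No.8 and Wnt5a at 3.24 and 4.40; the list stood apart under 7 alternatives. Of 18 cyclic AMP and CREB target genes past the floor, 4 were at least 2-fold higher in No.4 and 0 in No.8: Scg2, the signalling regulator gene Rgs2 (4.06-fold), the clock gene Per1 (3.16-fold) and the kinase gene Sik1 (2.05-fold). Of the same 18 genes, 11 were lower and 7 higher in No.8. Those higher, each under 2-fold, included Nr4a2 (0.96), Fos (0.79) and Gadd45b (0.74), named after their values were seen. The median of that list was 0.00 (32.9th percentile). Its mean of -0.28 stood apart (0.21th percentile), with Scg2 (-3.40) weighing most in it. Over genes past the floor the list's median was -0.26 (0.31th percentile). The cyclic AMP pathway components had a median of 0.10 and no member at 2-fold.

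In the Notch list (median -0.04), Hes1 and Nrarp were 2.68-fold and 2.57-fold higher in No.8. In the list of BMP and TGF-beta response genes (median 0.13), Fst, the activin subunit gene Inhba (4.37-fold) and Tgfb2 (3.66-fold) were higher in No.8, while Id3 (-1.09) and Smad7 (-1.02, named after its value was seen) were at least 2-fold higher in No.4. Growth factors and receptors went both ways (median 0.03), with Fgf1 at least 5.58-fold higher in No.8 and Fgf9, Nrg1 (at least 3.59-fold) and Kitlg (4.59-fold) higher in No.4. The bounds of Fgf1 and Nrg1 were counted from the floor. Over its 24 genes past the floor this list turned to a median of -0.29 at the 0.04th percentile, with 14 of 24 lower in No.8. The list of glioma tumour genes had a median of -0.21 (0.56th percentile) over oncogenes and tumour suppressors alike. Its largest differences were those of Olig2, Ccnd2, which encodes cyclin D2 (3.50-fold higher in No.8), Nf1 (-0.85) and Mdm4 (-0.84).

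Interferon response genes had a median of -0.17 (0.12th percentile), but a mean of -0.04 at the 15.6th percentile, and went in both directions: Gbp5 was 3.15-fold higher in No.8, Ifit2 differed by 0.97, and Ifih1 was at 4.67 and 3.53. The antigen presentation list (median -0.04) and the list of cytokines and NF-kB targets (median 0.09) did not stand apart. Within them, Psmb10 was 2.33-fold, Il33 5.45-fold and Cxcl1 2.45-fold higher in No.8, and Ccl7 was 3.60-fold higher in No.4. Counted from 5.67, Il33 was at least 2.67-fold and Ccl7 at least 2.04-fold apart, while Gbp5 (1.60-fold) and Psmb10 (1.68-fold) did not reach 2-fold. Ion channel and transporter genes had a median of 0.02, with Slc6a6, the taurine transporter, higher in No.8 by 1.59 log2 units. Kcna1 and Scn7a (2.45-fold) were higher in No.4. Kcnj10 was at 4.18 and 5.33, both under 5.67, so its difference may lie near background. Hox genes had a median of 0.11 and imprinted genes of 0.04. The housekeeping list had a median of 0.02, with Tfrc, the transferrin receptor gene, as its exception at 6.56-fold higher in No.8.

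The agreement between features of the same gene was used as a technical check within the pair of arrays. For the 162 genes with 2 features past the floor, the differences of the 2 brightest features correlated with r = 0.651 across genes, and 119 of 160 with values other than 0 had the same direction. In 11 of these genes both features held the same pair of values, which raises the agreement.

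Runs of 25 neighbouring genes were examined because subclones of a tumour line can differ in copy number. The highest run extended from Rasl10b to Rps6kb1 in the GRCr8 gene order, with a median difference of 0.55 and 22 of its 25 genes higher in colony No.8. In 4 of 1000 shuffles of gene order the highest run was as large. With runs of 50 genes, the highest ended at the same gene and had a median of 0.40, which 0 of 1000 shuffles reached. With runs of 15 genes, the highest lay elsewhere, from Carmil1 to the histone gene H2ac4, with a median of 0.70 that 11 of 1000 shuffles reached. Histone genes were higher in No.8 as a family (median 1.04 over 12 genes), and single values of their near-identical copies are uncertain. How many histone genes this run holds was not examined, so it is not read as a copy number difference. The lowest run, from Inpp5f to Ctbp2, had a median of -0.36, and 121 of 1000 shuffles gave one as low.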

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

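With 1 array per colony no replicate could be left out, and the list below covers the alternatives of processing only. No paired analysis was possible because each colony had a single array and the labels give no replicate numbers. Centring, quantile normalization and loess moved neither count by 1.5 times, though centring turned the split from 322 and 284 to 294 and 311. No list that stood apart changed direction under any alternative run. The median of all genes past the floor was 0.04 as deposited and 0.05 after quantile normalization. The counts of genes higher in No.8 and No.4 depended on the size asked for, as their construction implies: 1093 and 878 at 1.5-fold, 59 and 37 at 4-fold, and 87 and 80 with an offset of 64, which shrinks differences of dim genes. A floor at the upper quartile left 214 in each direction, and a floor at the 99th percentile of olfactory receptor genes, chosen after seeing the data, left 269 and 249; with levels under the floor raised to it, also chosen after seeing the data, these were 288 and 267, and Wnt5a (0.07), Gfap (0.84) and Ifih1 (-0.34) no longer reached 2-fold. With levels raised to 5.67, the 99th percentile of olfactory receptor genes and likewise chosen after seeing the data, 18 of the 95 named genes at 2-fold no longer reached it, and Tagln, Wnt5a, Kcnj10, Gfap and Ifih1 were at 0. Of the 195 named genes, 39 that reached 2-fold no longer did so with the offset, and 156 stayed on their side of 2-fold; under loess, quantile normalization and the mean of features all 195 did. The cell adhesion median lost its place outside the random range over genes past the floor (0.0021), with the offset (0.019), against unmatched lists (0.16) and, chosen after seeing the data, without genes of 2 or more lists (0.11); its cause was not tested. The interferon response list did so with the mean in place of the median (-0.038). With the mean, 8 lists stood above the range in place of 3 and 6 below it in place of 5, with the oligodendrocyte lineage (-0.23) and the cyclic AMP and CREB targets (-0.28) gained. Over genes past the floor, 9 stood below it in place of 5, among them the cyclic AMP and CREB targets (-0.26), the oligodendrocyte lineage (-0.33), Schwann and neural crest genes (-0.29) and the growth factors and receptors (-0.29). The correlation between features of the same gene was 0.406 with no floor and 0.802 with a floor at the upper quartile, and the cause was not tested. Over all measured genes the lowest run of neighbouring genes was -0.36, which 12 of 1000 shuffles reached. The Wnt pathway components, just inside the random range, lay above it under 7 of the alternatives. With the mean, the lists of neural stem and progenitor genes (0.21), BMP and TGF-beta response (0.25) and smooth muscle and pericyte genes (0.30) also stood above the range, and cholesterol synthesis (-0.16) stood below it against unmatched lists; without genes of 2 or more lists the BMP and TGF-beta response median was 0.26, above the range.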

Other observations

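Chosen only after the results they bear on had been seen were the families by symbol prefix, the tests of scaling for all 3 patterns, the test of shared probes for the NRF2 list, and the test along 4 parts of the chromosome, since runs of neighbouring genes on it had been seen; the genes named in this part were also chosen after their values were seen.

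Among 30 gene families defined by symbol prefix, 8 stood apart from level-matched random lists, where 1.5 would be expected by chance for independent sets of unrelated genes. Members of a family can vary together, which the random lists leave out, so 1.5 may be too low. Core histone genes were higher in colony No.8: the median difference over 12 genes was 1.04, and 5 of the 8 past the floor reached 2-fold, with H2ac4 at 7.81 and 9.53 and H2ac20 at 5.12 and 6.63. Histone genes have near-identical copies, so their single values are uncertain. RNA-binding proteins of the splicing machinery went the same way, with medians of 0.34 over 18 hnRNP genes (Hnrnpm 0.92) and 0.40 over 11 SR splicing factors (Srsf3 1.14). Kinesins (median 0.21) and aminoacyl tRNA synthetases (0.19) were higher in No.8, as were collagens (0.32), which the matrix list already holds in part. Cytosolic ribosomal protein genes were lower in No.8 by a small amount, with a median of -0.21 over 144 genes, 116 of them below 0, and -0.19 after quantile normalization. The 144 include genes that are copies by symbol, such as Rpl29l1 and Rps26l5. Close copies can share signal, so the 116 do not count as independent genes. The 246 genes named as zinc finger proteins had a median of -0.08.

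The lower level of NRF2 and glutathione genes in colony No.8 was followed up with a second list of 35 NRF2 targets. Of its 31 measured genes, 25 were lower in No.8, and the median was -0.31. The list's percentile among random lists was 0, as lower levels of NRF2 target genes as a set would predict. Osgin1 (-1.43), Aox1 (-1.32), Taldo1 (-1.21) and Gstm7 (-1.08) reached 2-fold and 0 genes did so in the other direction. The largest differences in that other direction were those of Cbr1 (0.77) and Ugdh (0.69). Scaling that depends on level is argued against, since the trend of the difference on level had a median of -0.0057 at the levels of the 23 members, against a list median of -0.44. Probes shared between copies of the Gst, Mt, Gpx and Akr families do not account for the pattern either, since the 10 members outside them had a median of -0.51 at the 0.03th percentile. Lower activity of the NRF2 pathway in colony No.8 may be considered as a hypothesis, tested here only through the RNA levels of the second list; a passing difference between 2 cultures in oxidative state or feeding stays open, since the design has no second culture of either colony.

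Genes past the floor on the chromosome that carries Antxr1, Plxnd1, Ccnd2 and Kcna1 in the GRCr8 gene order had a median difference of 0.18 over 602 genes, against 0.03 for all other genes and 0.08 for the next highest of 21 chromosomes. In 0 of 1000 shuffles was any chromosome median as high, and the percentile among gene sets matched on level was 100, which argues against scaling between the arrays that depends on level. An effect on the chromosome's features whatever their RNA level stays open. Its 512 genes below the floor had a median difference of 0.030, within the range of random sets, the outcome set beforehand to count against such an effect. Their median level of 3.13 lay below the 95th percentile of olfactory receptor genes (4.43). Whether a shift would show at such levels was not measured, so the result was called undecided after it had been seen. The shift stood above the middle 95% of random gene sets in 3 of 4 equal parts of the chromosome (medians 0.22, 0.09, 0.28 and 0.17). These parts re-cut the same genes for whose high median the chromosome had been picked. Their upper random limits lay near 0.11, so most parts were likely to pass. The split shows a shift spread along the chromosome, but it cannot decide on a difference in copy number. A gain in No.8 or a loss in No.4 is a candidate explanation that expression data alone cannot decide, and single genes such as Kcna1 ran strongly against it.

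Features without a gene name fell into 2 parts that behaved differently. Those with identifiers below the first named feature were lower in No.8: of 2625 past the floor, 414 were at least 2-fold lower in No.8 and 70 at least 2-fold higher, with a median of -0.28, while the other 5228 unnamed features gave 135 and 115. Scaling that depends on level is argued against, since named features matched on level had a median of 0.07 and the block lay at percentile 0 of 1000 matched draws. Features listed more than once do not account for it, since 85.8% of the 2-fold features were still lower in No.8 with each pair of values counted once. What these features target is not known here, so no biological explanation was tested and their identity stays open.

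In addition, 1320 of the 36685 features (3.60%) held exactly the same value in both arrays, and 1428 repeated the pair of values of an earlier feature. Cdkn2a, a tumour suppressor gene often lost in gliomas, was below the floor in both colonies, at 3.85 and 3.68.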
